A study of Homo sapiens with 6 samples.

How the data were processed

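RNA sequencing libraries from the human hepatoma line HepG2.2.15 were analysed, 6 in all. Of these, 3 were labelled as control cells carrying an empty lentiviral vector and 3 as cells carrying a lentiviral ADH4 construct. Groups and replicate numbers were taken from the labels. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

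Each library had its own deposited table with a count and an FPKM per gene symbol, per the file headers. The counts are whole numbers without normalization, and HISAT2, featureCounts and the genome build GRCh38 are named in the submitters' processing notes, with no version or role. The annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of a partner on the other strand cannot be told apart. The deposited FPKM values equalled count divided by a whole-number gene length and by a library total. This relation gave 1 length for 16324 of the 16325 genes with a count, within a relative tolerance of 0.0001. FPKM served only to recover gene lengths and library totals, and every test used the counts. The tables held 19225 gene symbols, of which 2900 had no count in any library and 12 were calendar dates in place of symbols. They held no mitochondrially encoded gene. GENCODE release 29 (GRCh38) gave a position for 18802 symbols.

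Total counts ranged from 29724940 to 42080325 per library, so that 3 counts, the upper limit allowed by a count of 0, corresponded to 0.0713 to 0.101 CPM (counts scaled to a common library total). Such limits cover counting error only. Replicate libraries were compared by chi-square over genes with at least 20 counts. Their chi-square per degree of freedom lay between 3.69 and 14.9, above sampling noise in each pair, so no pair was counted as 1 library. This does not show that the libraries came from separate cultures.

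Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which kept 13126, libraries were scaled by TMM, and groups were compared by the quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term. Fold changes are the libraries labelled ADH4-overexpressing minus the libraries labelled control. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM with their SD over 3 libraries. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. No block was used, because the labels give no batch or pairing.

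Gene lists were fixed before the data were examined, as were the tests, the groups and most of the other settings. They covered alcohol and aldehyde dehydrogenases with CAT and AKR1A1, retinoid metabolism, hepatocyte secreted proteins, liver transcription factors, oncofetal markers, bile acids, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, drug-metabolizing enzymes, glycolysis and hypoxia, DNA replication, mitosis, epithelial-mesenchymal transition and matrix, interferon-stimulated genes, antigen presentation, inflammation, the unfolded protein response with amino acid stress, NRF2, metallothioneins, p53, Wnt, YAP and TGF-beta, immediate early genes, hepatitis B virus host factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, core and linker histones and 3 sets of markers of other cell types. Each list with at least 3 measured genes was tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01), adjusted over the 31 lists. The same test was applied to the tested genes of 23 chromosomes. Camera with an estimated correlation and fry were alternatives.

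The genes named were ADH4, the 8 genes with the highest and the 8 with the lowest log2 fold change among those past the threshold with a symbol that is no clone or LOC name and no annotated pseudogene, at least 5 CPM in the higher group and no overlap between groups, the 4 genes with the smallest p, up to 4 members of each list with the smallest p, and the measured members of the alcohol and aldehyde dehydrogenase list. FAM65B met the rule but has no position in the annotation. Some genes that this rule selected are not reported here. Other names were chosen after their values were seen and are given as such.

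Other settings tried were DESeq2 size factors, upper-quartile scaling, total counts without a composition factor, ADH4 and the 10 most abundant genes left out of library sizes, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were an exchange of the ADH4 counts between same-numbered libraries, offsets for gene length and GC content fitted per library with splines of 4 degrees of freedom, and a 2-fold threshold. GC content came from the GENCODE transcript of each symbol closest to the recovered length, and 98.1% of the tested genes had both values.

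The pipeline was tested on simulated data for the comparison of the 2 groups, with 13066 genes passing the filter and 200 genes changed. It called 52% of the genes simulated with a 1.25-fold change, 84% at 1.5-fold, 84% at 2-fold and 100% at 4-fold. It called 12 unchanged genes, 6.4% of its calls. These calls include genes of the liver transcription factor list, which was shifted as well. Camera called that list and 1 other, which was not shifted. Tables were read with Python 3.11.15 and pandas 2.3.3.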

Results

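Transcriptomes of HepG2.2.15 cells labelled as control and as ADH4-overexpressing were compared by RNA sequencing. HepG2.2.15 is a human hepatoma line derived from HepG2 that carries integrated hepatitis B virus genomes and produces virus. ADH4 encodes the pi class alcohol dehydrogenase of the liver, which oxidises alcohols and retinol. The series held 3 libraries labelled control, from cells with an empty lentiviral vector, and 3 labelled ADH4-overexpressing (hereafter labelled OE), from cells with an ADH4 lentivirus. Total counts were 34253261, 34528289 and 42080325 in the libraries labelled control 1, 2 and 3, and 34092621, 34833579 and 29724940 in those labelled OE 1, 2 and 3. Levels are given as TMM-scaled CPM, counts scaled to a common library total. Between 14575 and 15107 genes had a count in a library. The most abundant gene, EEF1A1, took 1.1% to 1.32% of counts.

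ADH4 (ENSG00000198099.8, chromosome 4, 99123657 to 99157792, minus strand, GRCh38) was examined first as the targeted gene. As deposited, its counts were 135, 136 and 125 in the libraries labelled control and 5396, 5867 and 6876 in those labelled OE. Its level was 191 ± 40.8 CPM in the libraries labelled OE and 3.53 ± 0.54 CPM in those labelled control (SD, n = 3 each). The log2 fold change was 5.76 (SE 0.15, edgeR quasi-likelihood adjusted p = 3.1e-13). ADH4 was, however, the 1 gene of 16325 whose deposited FPKM values and counts implied no common gene length. The library totals behind the FPKM values exceeded the summed counts by 5261, 5731 and 6751 in the libraries labelled control 1, 2 and 3. They fell short by the same numbers in the libraries labelled OE 1, 2 and 3. These are the differences in ADH4 count between libraries of the same number. With the ADH4 counts exchanged between same-numbered libraries, counts and totals matched in 6 of 6 libraries, ADH4 had a length of 2100 bases, and its log2 fold change was -5.28 (SE 0.065, edgeR adjusted p = 2.87e-18). The tables behind the FPKM values therefore had ADH4 high in the libraries labelled control. The level, SD and SE given above for the deposited counts scaled each ADH4 count by the total of another library. They are thus no valid measure of ADH4. There the libraries labelled control had 5396, 5867 and 6876 ADH4 counts, and those labelled OE had 135, 136 and 125. Correct labels would give the opposite, so these values argue against the labels. This rests on ADH4 alone and does not prove that the labels were reversed. Every direction given here is by label, higher or lower in the libraries labelled OE than in those labelled control. If the labels were reversed, these directions would turn.

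**Figure D1:**
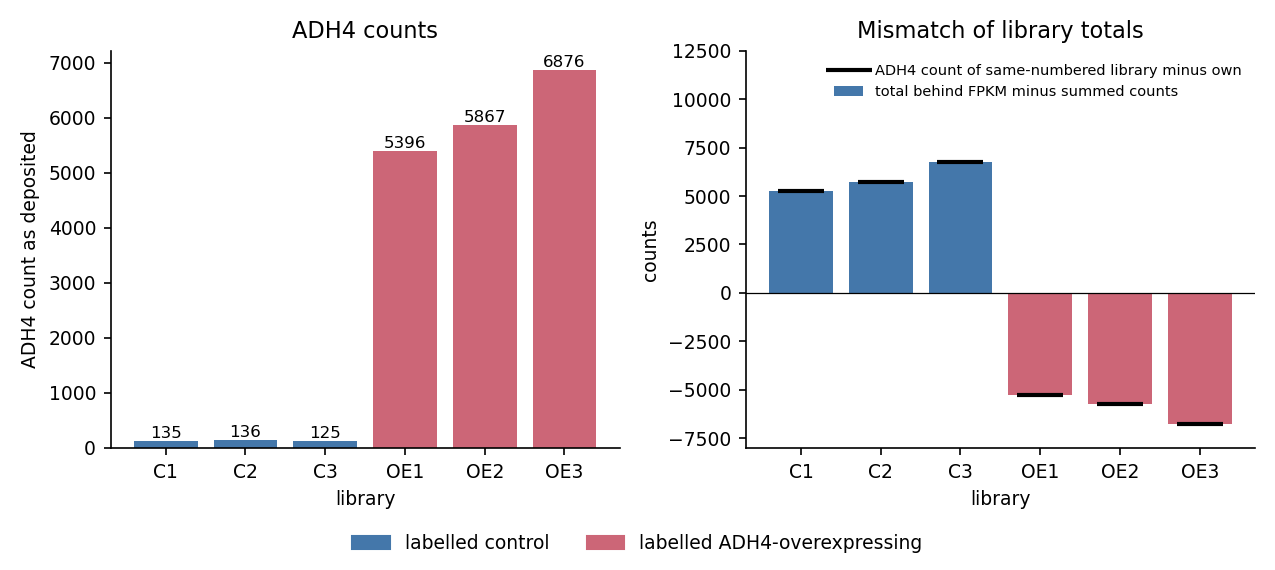
ADH4 counts as deposited in each library (left, bars) and the mismatch between the library total behind the FPKM values and the summed counts (right, bars, in counts), with the ADH4 count of the same-numbered library of the other group minus the library's own as black marks. C1 to C3 are the libraries labelled control and OE1 to OE3 those labelled ADH4-overexpressing; bars and marks coincide at 5261, 5731 and 6751 counts above and below 0.

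The transcriptomes of the groups differed widely. Of 13126 genes tested, 7473 (56.9%) passed an edgeR adjusted p of 0.05, 3696 of them higher and 3777 lower in the libraries labelled OE. With total counts and no composition factor, 2875 were higher and 4578 lower, so the balance between directions depends on the scaling. Most changes were small, and 506 genes changed at least 2-fold, 113 of them higher and 393 lower. Of the 506, 189 reached 5 CPM in the higher group. With only genes of at least 1 CPM in 3 libraries, 75 were higher at least 2-fold. The groups did not overlap in 8236 genes (62.7%), where chance gives 10%. The first principal component held 64.4% of the variance and separated the groups. The coefficient of variation between libraries of a group, from the common edgeR dispersion, was 6.02%. It is termed biological in edgeR but may be technical here.

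Among the genes with the highest fold changes in the libraries labelled OE was AFP (chromosome 4, 73431138 to 73456174), the fetal serum protein used as a liver cancer marker. It reached 91.6 ± 12 CPM against 25 ± 2.41 CPM (SD, n = 3 each), a log2 fold change of 1.87 (SE 0.085, edgeR adjusted p = 1.6e-10). DKK4, a secreted Wnt antagonist, had 9.17 ± 0.496 CPM against 1.83 ± 0.552 CPM. HSPA1B, an inducible heat shock chaperone, had 195 ± 2.33 CPM against 65.8 ± 16.5 CPM, although reads can be shared with its near-identical copy HSPA1A. The peptidase DPEP1, the helicase-like DQX1, the serpin SERPINA11 and the homeobox gene HOXD1 rose by 2.42, 2.17, 1.63 and 1.53 on the log2 scale. SULT1A3, a sulfotransferase with a near-identical copy (SULT1A4), had a log2 fold change of 3.83, but 1 library carried it. Its levels were 103 CPM in the library labelled OE 1 and 5.87 and 4.48 CPM in the others. Without that library the log2 fold change was 0.97, and limma-voom and robust dispersions ended the call (adjusted p = 0.09 and 0.13).

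The lowest fold changes were those of CATSPERG, a subunit of a sperm calcium channel, at 2.2 ± 0.499 CPM in the libraries labelled OE against 22.3 ± 1.39 CPM (log2 fold change -3.33, SE 0.13, edgeR adjusted p = 4.7e-11), and of AHNAK2, at 2.86 ± 0.948 CPM against 17.9 ± 1.97 CPM. MSN, which links actin to the membrane, FAM65B, the histone deacetylase HDAC9 and the retinol dehydrogenase DHRS9 changed by -2.58, -2.49, -2.39 and -2.36 on the log2 scale, and GFPT2, which starts hexosamine synthesis, by -2.11. SLC7A11, the cystine transporter (chromosome 4, 138164097 to 138242349), fell from 91.7 ± 10.6 CPM in the libraries labelled control to 20.6 ± 2.2 CPM (log2 fold change -2.15, SE 0.083, edgeR adjusted p = 4.7e-11). CDH17, a cadherin of intestinal epithelium (chromosome 8, 94127171 to 94217303), stood at 33.9 ± 1.16 CPM against 102 ± 6.09 CPM, and the matrix metalloproteinase MMP7 (chromosome 11, 102520508 to 102530753) at 36.3 ± 1.59 CPM against 91.8 ± 1.96 CPM. These 2, with ADH4 and SLC7A11, had the smallest p-values of all genes. CATSPERG and SLC7A11 have an antisense partner in the annotation, and AHNAK2 overlaps the protein-coding PLD4 on the other strand. Of 145 genes selected by the naming rule, 57 overlap another annotated gene, and 21 overlap a protein-coding one.

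Camera called 12 of the 31 gene lists, 6 in each direction, and other groupings of the 6 libraries into 3 and 3 gave up to 12 called lists. Proteins that hepatocytes secrete were higher in the libraries labelled OE. Of 31 measured members of that list, 27 were higher and 2 lower, counts that were the same adjusted over the list alone, with a median log2 fold change of 0.49 (camera adjusted p = 3.35e-16). The 3 fibrinogen genes, neighbours on chromosome 4, rose together. FGA rose to 338 ± 20.9 CPM from 152 ± 8.27 CPM, FGB to 187 ± 7.71 CPM from 93.5 ± 2.59 CPM and FGG to 283 ± 7.64 CPM from 152 ± 1.13 CPM (SD, n = 3 each). Albumin (ALB) had 130 ± 5.86 CPM against 66.4 ± 0.56 CPM (log2 fold change 0.97, SE 0.047, edgeR adjusted p = 2.8e-10). This list held its call with an estimated correlation (adjusted p = 0.027), as did those of matrix genes and of YAP and TGF-beta genes, and no other list did. Liver transcription factors were not called as a set (9 of 22 higher and 4 lower, the same adjusted over the list alone, camera adjusted p = 0.22). Among them HNF4A rose to 262 ± 5.22 CPM from 165 ± 7.21 CPM and CEBPA to 258 ± 7.36 CPM from 148 ± 7.38 CPM, while CEBPB fell to 120 ± 7.57 CPM from 249 ± 34.6 CPM. Of 19 oncofetal markers 6 were higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.18). AFP, TSPAN8 and AKR1B10 were highest among those named.

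Genes of DNA replication and S phase rose in the libraries labelled OE in 33 of 36 members and fell in none, and in 34 adjusted over the list alone. The median log2 fold change was 0.47 (camera adjusted p = 3.35e-16). The call was lost with an estimated correlation (adjusted p = 0.27). MCM5, MCM2 and MCM7, subunits of the replicative helicase, had log2 fold changes of 0.87, 0.71 and 0.56, and the flap nuclease FEN1 had 239 ± 4.93 CPM against 128 ± 16 CPM. FEN1 overlaps FADS2, MCM2 overlaps TPRA1 and MCM7 overlaps AP4M1, so their counts are less certain. Mitotic genes were not called as a set, with 11 of 34 higher and 6 lower (the same adjusted over the list alone, camera adjusted p = 0.3). They were called with offsets for gene length and GC content (median 0.14). CDC20, AURKB, PLK1 and CCNB1 rose by 0.59, 0.59, 0.47 and 0.34 on the log2 scale. Of 7 core and linker histone genes 2 were higher and 1 lower, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.86). HIST2H2AC, a core histone gene, was the higher of the 2, with 3.2 ± 0.559 CPM against 1.46 ± 0.133 CPM, and the linker histone gene HIST1H1C lost its call without the library labelled control 2 or 3 or OE 2 or 3.

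**Figure D2:**
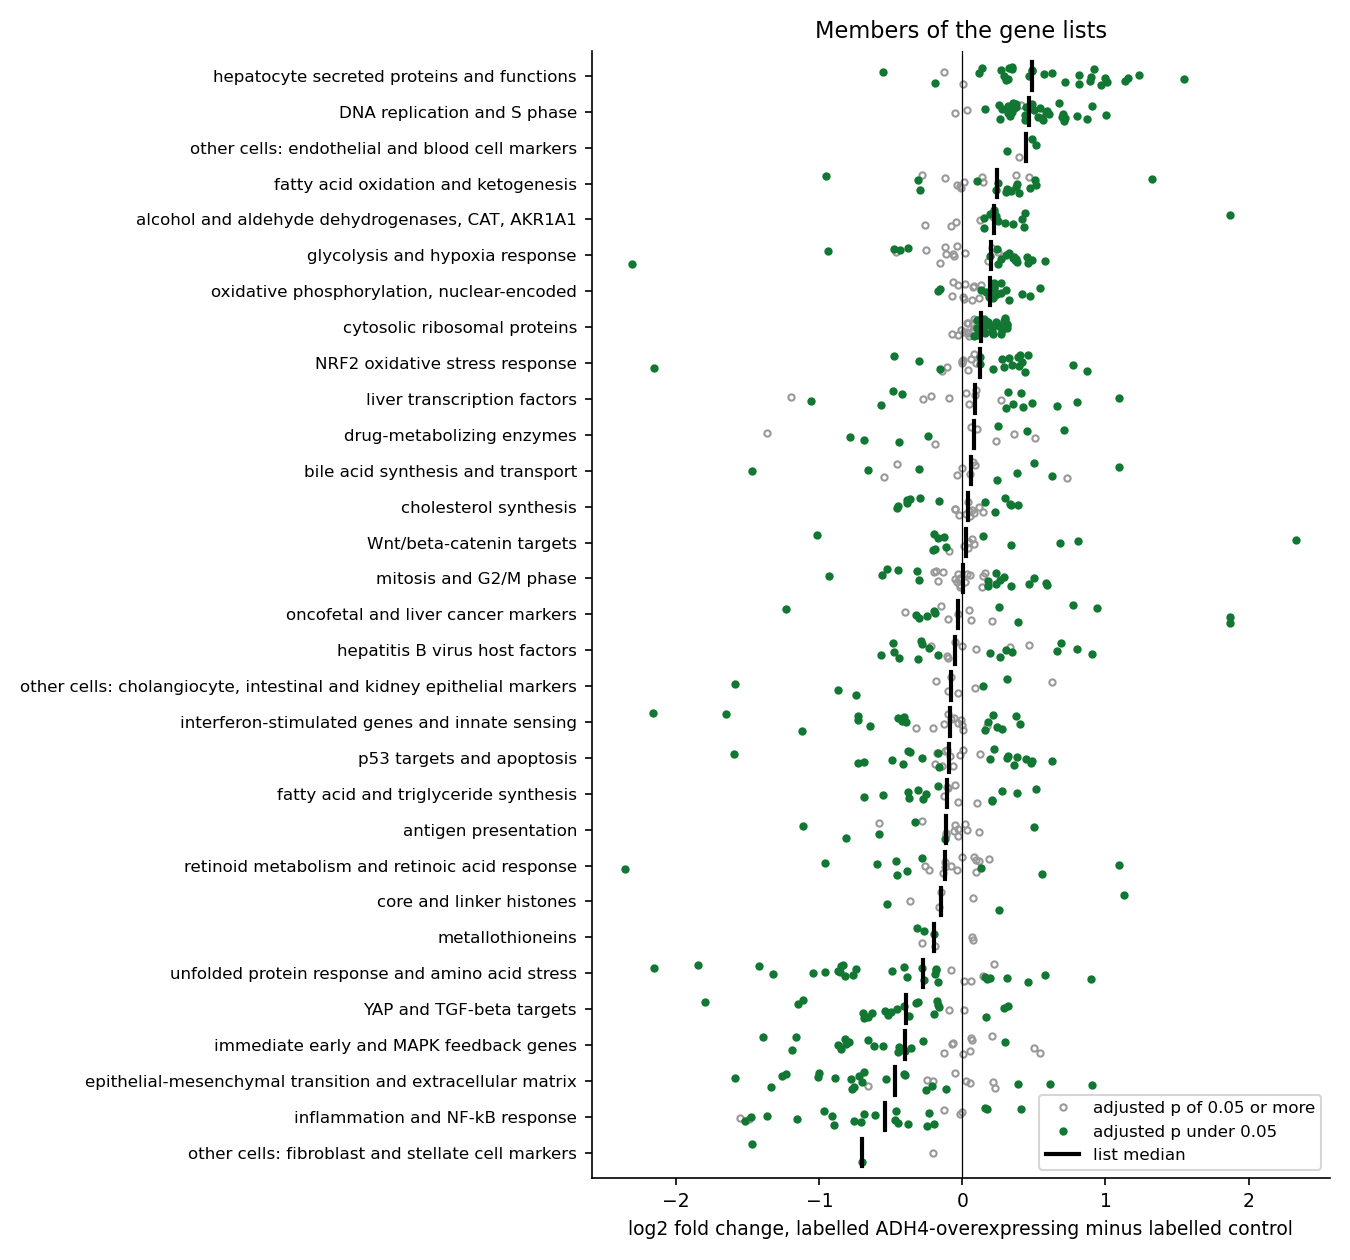
Log2 fold change of each measured member of the 31 gene lists (horizontal axis, libraries labelled ADH4-overexpressing minus those labelled control), with lists ordered by their median (black bars). Filled points passed an edgeR adjusted p of 0.05 and open points did not; hepatocyte secreted proteins and DNA replication genes have medians of 0.49 and 0.47, and inflammation genes -0.54. Medians near 0 can change sign when a library is left out.

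Genes of the epithelial-mesenchymal transition and extracellular matrix list were lower in the libraries labelled OE, with 19 of 30 lower and 3 higher, the same adjusted over the list alone (median log2 fold change -0.47, camera adjusted p = 1.79e-09, and adjusted p = 0.03 with an estimated correlation). The integrin ITGA3 fell from 268 ± 15.4 CPM in the libraries labelled control to 133 ± 3.34 CPM, and the integrin ITGB1 and MMP7 changed by -0.72 and -1.34 on the log2 scale. The list of YAP and TGF-beta targets also holds pathway members such as TGFB2 and TEAD1. Its genes were lower in 19 of 24 and higher in 3, the same adjusted over the list alone (median -0.39, camera adjusted p = 6.08e-07, and adjusted p = 0.042 with an estimated correlation). INHBE, an activin subunit, had 39.8 ± 2.53 CPM against 139 ± 20.1 CPM. PMEPA1, a feedback inhibitor of TGF-beta signalling, TGFB2 and TEAD1 changed by -1.15, -1.12 and -0.70 on the log2 scale.

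Inflammation and NF-kB genes were lower in 18 of 26 members in the libraries labelled OE and higher in 3, with 19 lower and 3 higher adjusted over the list alone. Their median log2 fold change was -0.54 (camera adjusted p = 1.24e-06). This call was lost with an estimated correlation (adjusted p = 0.3). The chemokine CXCL8 had 47.2 ± 3.7 CPM against 131 ± 16.6 CPM, and LCN2, CCL20 and TNFAIP3 changed by -0.97, -0.91 and -0.76 on the log2 scale. Immediate early and MAPK feedback genes were lower in 16 of 27 members and higher in 1, the same adjusted over the list alone (median -0.40, camera adjusted p = 4.75e-07, but adjusted p = 0.27 with an estimated correlation). KLF6 and EGR1, transcription factors, changed by -1.16 and -1.19, and DUSP6 and SPRED1, brakes on MAPK signalling, by -0.81 and -0.79. Interferon-stimulated genes were not called (7 of 28 higher and 10 lower, camera adjusted p = 0.6), and neither were antigen presentation genes (1 of 17 higher and 5 lower, camera adjusted p = 0.13). Both pairs of counts were the same adjusted over the list alone. IRF1 and OAS1 changed by -0.45 and -0.39, IFITM3 and ISG15 by 0.27 and 0.40. B2M, the light chain of class I molecules, fell from 355 ± 7.2 CPM in the libraries labelled control to 237 ± 3.13 CPM, and NLRC5, HLA-B and PSMB10 changed by -1.12, -0.82 and 0.50.

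**Figure D3:**
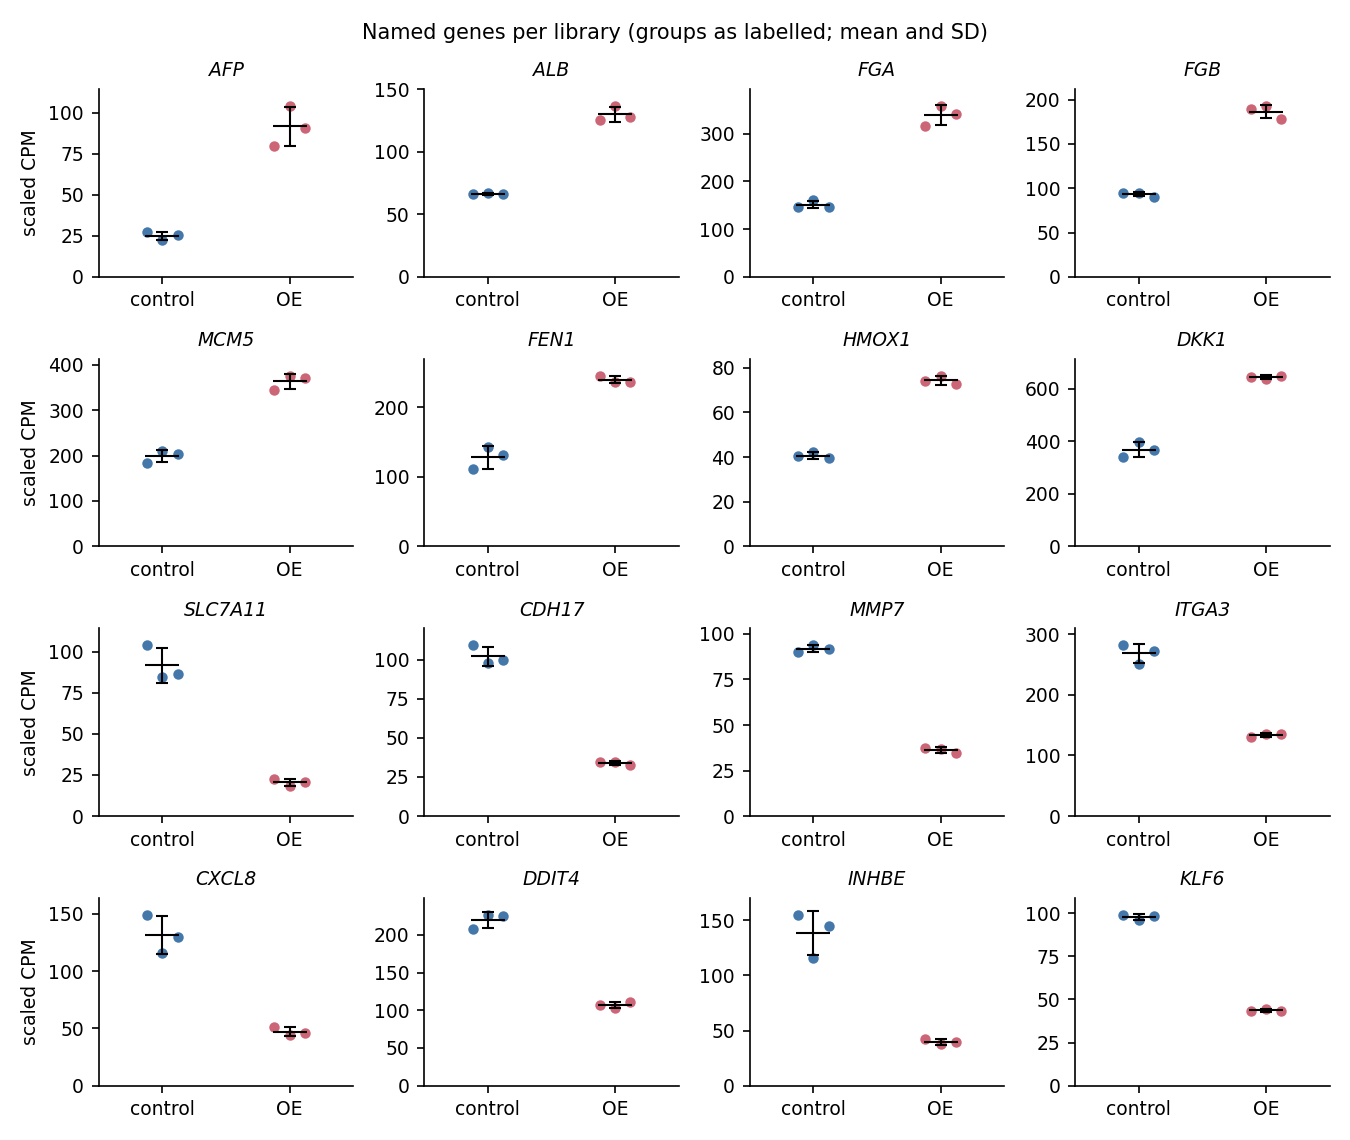
Level of 16 genes in each library (vertical axes, TMM-scaled CPM, from 0), in the libraries labelled control (blue) and labelled ADH4-overexpressing (OE, red), with the mean and SD of 3 libraries in black. The groups do not overlap in any of the 16 genes, with AFP at 25 against 91.6 CPM and SLC7A11 at 91.7 against 20.6 CPM.

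The list of the unfolded protein response and amino acid stress was lower in the libraries labelled OE in 22 of 34 members and higher in 7, with 23 lower and 7 higher adjusted over the list alone (median -0.28, camera adjusted p = 1.15e-06, but adjusted p = 0.13 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell from 220 ± 10.6 CPM in the libraries labelled control to 107 ± 4.1 CPM, and ATF4, the transcription factor of the amino acid response, from 633 ± 33.4 CPM to 373 ± 5.5 CPM. GDF15 changed by -0.83 on the log2 scale. NRF2 targets were higher in 15 of 28 members and lower in 4, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.017, but adjusted p = 0.16 with an estimated correlation). HMOX1, which degrades heme, had 74.3 ± 1.95 CPM against 40.7 ± 1.4 CPM, and NQO1 and AKR1B10 rose by 0.44 and 0.77, whereas SLC7A11, on both stress lists, was the lowest. The metallothionein list was not called (0 of 7 higher and 3 lower, the same adjusted over the list alone, camera adjusted p = 0.44). Its 3 lower members were the zinc transporters SLC30A1 and SLC39A10 and the transcription factor MTF1, at -0.27, -0.32 and -0.20, and the metallothionein MT1E did not pass (-0.19, edgeR adjusted p = 0.17). MT1E ran from -0.31 to -0.09 with a library left out and was called without the library labelled control 2 (adjusted p = 0.013). With offsets for gene length and GC content, SLC39A10 and MTF1 stood at 0.04 and 0.02, and MTF1 lost its call without the library labelled control 1 or 3 or OE 2 or 3 (adjusted p from 0.074 to 0.12). Of 30 p53 and apoptosis genes 10 were higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.65). PMAIP1, a promoter of apoptosis, had 12.5 ± 1.12 CPM against 38 ± 3.35 CPM, and GADD45A, FDXR and MCL1 changed by -0.69, 0.49 and -0.37.

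The list of other alcohol and aldehyde dehydrogenases, which also holds CAT and AKR1A1, was slightly higher in the libraries labelled OE. Of 18 measured members 13 were higher and 0 lower, the same adjusted over the list alone (median 0.22, camera adjusted p = 0.004, but adjusted p = 0.14 with an estimated correlation). ALDH2, the mitochondrial enzyme that clears acetaldehyde, had 286 ± 2.15 CPM against 232 ± 6.14 CPM (log2 fold change 0.30, SE 0.038, edgeR adjusted p = 5.4e-06). ALDH18A1, ALDH4A1, ALDH1B1, ALDH3A2, ALDH7A1, CAT and AKR1A1 had log2 fold changes between 0.22 and 0.44. ALDH8A1 rose by 1.87 from a low level of 0.329 ± 0.138 CPM. ADH5, ADH6, ALDH5A1 and ALDH9A1 (0.15, 0.43, 0.15 and 0.19) passed, but not with total counts as the scaling (adjusted p of 0.08, 0.052, 0.19 and 0.098). ALDH1A1, ALDH1A3, ALDH3A1, ALDH3B1 and ALDH6A1 did not pass, with values from -0.26 to 0.21, although ALDH1A1 was called lower with total counts (-0.15, adjusted p = 0.0046). ADH6, ALDH5A1 and ALDH9A1 also lost their calls without the library labelled control 3 (adjusted p of 0.11, 0.076 and 0.076), and each without 1 or more libraries labelled OE (adjusted p from 0.053 to 0.19). Retinoid genes were not called (3 of 23 higher and 7 lower, the same adjusted over the list alone, camera adjusted p = 0.15). DHRS9 and the binding protein CRABP2 changed by -2.36 and -0.96, and RBP4 by 0.56.

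Lipid and drug metabolism showed no called list. Fatty acid oxidation genes were higher in 13 of 26 members and lower in 3 in the libraries labelled OE, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.074). ECI1, ETFB and ACAA1 rose by 0.51, 0.51 and 0.47, and ACSL1, which activates fatty acids, changed by -0.95. At their smallest under other settings these were 0.27, 0.24, 0.25 and -0.86. In fatty acid synthesis 5 of 19 were higher and 8 lower, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.53), with ELOVL6, FADS2, ELOVL5 and DGAT1 at -0.69, -0.55, -0.37 and 0.51. Cholesterol synthesis had 6 of 24 higher and 7 lower (camera adjusted p = 0.87). Its regulator SREBF2 and CYP51A1 stood at -0.29 and -0.46, EBP and NSDHL at 0.33 and 0.39. Bile acid genes were higher in 5 of 16 and lower in 3 (camera adjusted p = 0.65), with HSD3B7, CYP27A1, ABCC2 and ABCB4 at 0.62, 0.24, -0.31 and -0.66. Drug-metabolizing enzymes were higher in 3 of 14 and lower in 4 (camera adjusted p = 0.87). Among them SULT1A1, SULT2A1, CYP2B6 and CYP3A5 stood at 0.45, 0.71, -0.44 and -0.69. These last 3 pairs of counts were the same adjusted over the list alone.

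In central metabolism, nuclear-encoded genes of oxidative phosphorylation were higher in the libraries labelled OE in 19 of 32 members and lower in 2, or 20 and 2 adjusted over the list alone. The median was 0.19 (camera adjusted p = 0.0011, but adjusted p = 0.14 with an estimated correlation), and offsets for gene length and GC content ended the call (adjusted p = 0.065). CYC1, NDUFB10, NDUFS3 and UQCRC1 rose by 0.54, 0.47, 0.42 and 0.31, and at the least by 0.29, 0.21, 0.20 and 0.09 under other settings. Mitochondrially encoded transcripts had 0 measured members and were not tested. Ribosomal protein genes were higher in 28 of 45 members and lower in 0, the same adjusted over the list alone (median 0.13, camera adjusted p = 0.00033, but adjusted p = 0.43 with an estimated correlation). With the offsets, their median was 0.006 and the test pointed down. RPS2, RPSA and RPS19 rose by 0.31, 0.30 and 0.29. Glycolysis and hypoxia genes were higher in 15 of 32 members and lower in 5, the same adjusted over the list alone (median 0.20, camera adjusted p = 0.15). The list was called without the library labelled control 2 (median 0.32, adjusted p = 0.0036), and its median was 0.07 without control 1 and 0.12 without OE 2. ENO1, GPI and PFKL rose by 0.45, 0.46 and 0.38, while VEGFA, an angiogenic factor, had 98.6 ± 6.99 CPM against 189 ± 18.9 CPM.

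Wnt targets were not called (5 of 18 higher and 7 lower, camera adjusted p = 0.26). The Wnt antagonist DKK1 rose in the libraries labelled OE to 645 ± 6.73 CPM from 369 ± 28.9 CPM, and SP5 and GLUL rose by 0.68 and 0.34 on the log2 scale. Host factors of hepatitis B virus were higher in 8 of 25 members and lower in 9 (camera adjusted p = 0.32). FEN1, CEBPA, HNF4A and LIG1 were the named members, all higher, LIG1 by 0.69. Among markers of other cell types, those of fibroblasts were not called and were lower in 2 of 3 measured genes (camera adjusted p = 0.3), COL1A1 and DES at -0.70 and -1.47, with PDGFRB not passing. DES was low, at 0.38 CPM against 1.04 CPM. Endothelial and blood cell markers were not called either and were higher in 3 of 4 (camera adjusted p = 0.13), LYZ, CD68 and VWF at 0.49, 0.51 and 0.31, and PECAM1 did not pass. LYZ was abundant in both groups, at 1050 CPM against 749 CPM. Of 11 listed fibroblast markers only 3 were measured, and of 12 endothelial and blood cell markers only 4. VWF lost its call when any 1 library was left out (adjusted p from 0.053 to 0.115), and with total counts VWF and VIL1 did not pass (adjusted p of 0.094 and 0.065) while PDGFRB did (adjusted p = 0.042), as it did without the library labelled OE 3 (adjusted p = 0.039). Without the library labelled control 2 the endothelial and blood cell list was called (adjusted p = 0.034). Cholangiocyte, intestinal and kidney markers were higher in 2 of 11 and lower in 3 (median -0.08, camera adjusted p = 0.04, but adjusted p = 0.37 with an estimated correlation). CDH17, MUC5AC, KRT7 and VIL1 stood at -1.59, -0.87, -0.74 and 0.14. That call was lost without the library labelled control 1 (adjusted p = 0.052) or labelled OE 1 (adjusted p = 0.077), where the median was 0.03 and 0.008. All counts of higher and lower members in this paragraph were the same adjusted over the list alone.

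Fold changes followed gene length and GC content. Across 10539 genes, which are not independent replicates, the Spearman correlation of the log2 fold change was -0.41 with length and 0.49 with GC. The shortest of 5 equal groups of genes had a median of 0.19 in the libraries labelled OE relative to those labelled control, and the longest -0.22. For GC content the medians ran from -0.27 in the lowest group to 0.19 in the highest. The trend was present in all 6 libraries, as correlations with the deviation from the mean of all libraries. For length they were 0.33 to 0.39 in those labelled control and -0.35 to -0.39 in those labelled OE. For GC they were -0.38, -0.60 and -0.32 in those labelled control 1, 2 and 3, and 0.38 to 0.49 in those labelled OE. The library labelled control 2 thus stood furthest out for GC. Deviations from a common mean balance out, so the opposite signs of the groups are partly built in. Offsets for both properties removed the trend (correlations of -0.005 and 0.02) and left 6110 genes called. Fitted to these same data, the offsets remove it by construction, along with any real group difference that follows length or GC. Of the 7473 genes called without them, 4824 were called and 4717 of these in the same direction. Ribosomal protein genes (median 837 bases), oxidative phosphorylation genes (971 bases) and hepatocyte secreted proteins (1678 bases) were short, and the matrix genes (3952.5 bases) long. Of the genes named, CYP27A1, EBP, NSDHL, IFITM3, ISG15, SLC30A1, RPS19, VIL1, AKR1A1 and HIST1H1C no longer passed with the offsets, while MT1E (-0.33), ALDH3A1 (-0.26) and ALDH6A1 (0.42) did. Of 122 genes selected by the naming rule and called in the same direction both ways, 25 shrank by more than 1.5 times with the offsets, among them ALDH2 (0.11), TEAD1 (-0.32), SPRED1 (-0.41), UQCRC1 (0.09) and RPS2 (0.09), and 5 grew by more than that factor. With the offsets, the lists of retinoid genes, mitosis, antigen presentation and endothelial and blood cell markers were called as well, at medians of -0.19, 0.14, -0.21 and 0.43.

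**Figure D4:**
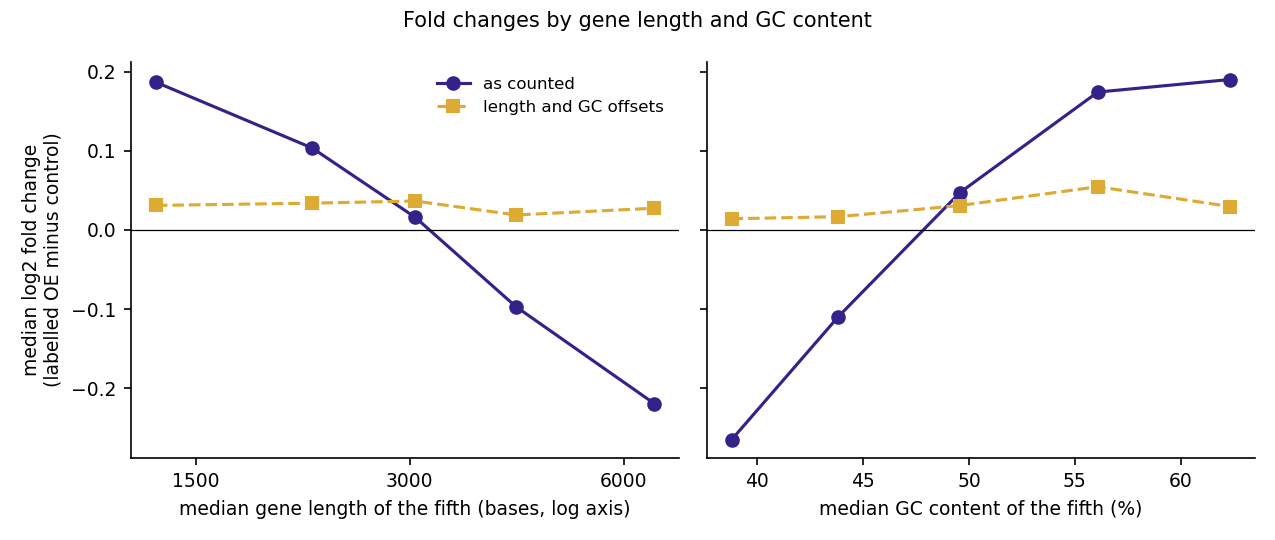
Median log2 fold change (vertical axis, libraries labelled ADH4-overexpressing minus those labelled control) of 5 equal groups of genes by length (left, bases, log axis) and by GC content (right, percent), as counted (circles) and with offsets for both (squares). As counted, medians run from 0.19 to -0.22 with length and from -0.27 to 0.19 with GC content.

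Chromosomes were compared as sets because derivatives of an aneuploid line can differ in copy number. Chromosome 4 stood lowest in the libraries labelled OE, with 226 of 427 genes lower and 38 higher, or 228 and 39 adjusted over the set alone (median -0.30, camera adjusted p = 2.76e-06). Chromosomes 18, 13, 10 and 5 were also called lower, and 19, 17, 16 and 22 higher, with medians from -0.15 to 0.13. None of the 9 calls held with an estimated correlation (adjusted p = 0.18 for chromosome 4), and only that of chromosome 4 held with offsets for length and GC content (median -0.14). Other groupings of the 6 libraries gave up to 8 called chromosomes. Total counts without a composition factor called 5 chromosomes. So did the data without the library labelled OE 2 or OE 3, and 4 were called without that labelled control 2. AFP, ALB and the fibrinogen genes, all higher by label, lie on chromosome 4.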

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

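The tests of the ADH4 mismatch were chosen after the result was seen, whereas those of the chromosomes, of the gene lists and of other groupings of the libraries were written down before their results. The offsets for gene length and GC content, on which the chromosome and list tests rest, were themselves chosen after the data were seen.

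The deposited FPKM values, used in no comparison, held a signal that the counts do not show. The library totals behind them differed from the summed counts by 5261, 5731 and 6751 counts in the same-numbered pairs 1, 2 and 3, each time by the ADH4 count difference of the pair. Rounding of the FPKM values is excluded, because the ADH4 length they implied deviated by up to 0.416 of itself between libraries. An exchange of the ADH4 rows between same-numbered libraries after the FPKM values were made accounts for the totals in 6 of 6 libraries. An exchanged row and reversed labels are not alternatives, and what remains open is whether the group labels were reversed. With the ADH4 counts exchanged back the log2 fold change was -5.28, so ADH4 was higher in the libraries labelled control. That is the direction reversed labels would give. Correct labels would give the opposite, so the exchanged-back ADH4 counts argue against the labels. No other gene in the tables reports the construct, so this rests on ADH4 alone and does not prove that the labels were reversed. If the labels were reversed, the directions of all other genes by label would be turned too.

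Chromosome 4 had the lowest median of the 23 chromosomes in the libraries labelled ADH4-overexpressing. With offsets for gene length and GC content its median rose from -0.30 to -0.14, between the bounds set before this test for and against such a bias, so the bias may account for part of the shift and cannot be told apart from a real one. The other 8 called chromosomes lost their calls with the offsets, with medians between -0.02 and 0.05. A lower copy number of the whole chromosome was tested in 8 bins along it, and the highest bin median with offsets was -0.094, neither below the bound of -0.1 in each bin nor above 0. The libraries labelled ADH4-overexpressing may hold fewer copies of chromosome 4, or the groups may differ in its regulation, and these explanations stay open, the last untested.

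Several gene lists moved together by label. With offsets for gene length and GC content, 10 of the 12 called lists (83.3%) kept their call and direction. The 2 that did not were oxidative phosphorylation and ribosomal protein genes, both of short genes. The length and GC trend as fitted by the offsets therefore does not account for all the calls. The offsets cover only that fitted trend, so they cannot exclude other technical differences between the groups. Other groupings of the libraries also gave up to 12 called lists. An effect of ADH4 and a difference between separately grown cell populations are confounded in this design, and neither was tested.

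The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7473 changed genes and the highest other split 1, so 1 of the 10 splits reached the count. For genes higher (3696) and genes lower (3777), 1 of the 10 splits reached each count, and the highest other split gave 1 in either direction. For chromosomes, 1 of the 10 splits reached the real 9, and the highest other gave 8. For gene lists, 4 of the 10 splits gave as many as the real 12, and the highest other gave 12.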

How the results depend on the processing

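The exchange of the ADH4 counts, the offsets for gene length and GC content and the 2-fold threshold were chosen after the data were seen. The number of changed genes stayed within 1.5 times of 7473 under each setting run, from 6110 with the offsets to 7561 with no filter, and from 6629 to 7408 with a library left out. DESeq2 gave 7309 and limma-voom 7429. ADH4 turned to -5.28 with its counts exchanged back, which the exchange itself produces, and lay between 5.58 and 5.87 with a library left out. The latter range used the ADH4 counts as deposited, so its narrowness says nothing about a rise of ADH4. Called lists numbered 12, against 3 with an estimated correlation, 23 with fry, which does not compare a list with other genes, and 11 to 14 with a library left out. Called chromosomes numbered 9, against 0 with an estimated correlation, 22 with fry, 5 with total counts, 1 with the offsets and 4 to 9 with a library left out, lowest without the library labelled control 2. Genes higher at least 2-fold numbered 113, and 75 with a filter of 1 CPM in 3 libraries, which tests 12139 genes. With the offsets SLC39A10 (0.0402) and MTF1 (0.0239) turned, as did the test of the ribosomal protein list but not its median (0.00606). Beyond these, the cause was not tested. Of the values of single named genes under other settings, 2386 kept their side of the threshold and direction, 48 lost and 8 gained a call. For lists these numbers were 371, 13 and 17. Most named genes were selected by fold change or p in these same data, and some settings nearly repeat the main fit. A high share of kept gene calls was therefore likely in advance and is no measure of robustness. Among lists not called, medians changed sign with a library left out (Wnt, cholesterol, drug, mitotic and oncofetal genes) or with the offsets (p53 and hepatitis B host factors). The median of the bile acid list, 0.06, turned to -0.004 under another setting. The replicate number as a block gave 7309 genes and ended the call of the NRF2 list (camera adjusted p = 0.052, and 0.015 to 0.16 over the other camera settings). Libraries of the same number did not deviate together (correlations of 0.04, -0.04 and -0.04), and 0 of 6 correlated best with their own number, so the numbers give no pairing. At 3 libraries per group and this depth, 52% of the smallest simulated changes were called. The simulation changed 200 genes and 1 list, against 7473 genes called in the data, so this share need not hold for the data.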

Other observations

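The 6 gene lists of these 2 paragraphs were chosen after the data were seen, and their p-values do not allow for that choice. They were adjusted together with the 31 others, and their directions are again by label. Heat shock chaperones and their cofactors, mitochondrial and endoplasmic reticulum members included, were higher in 16 of 20 members in the libraries labelled ADH4-overexpressing and lower in 0 (median log2 fold change 0.38, camera adjusted p = 2.74e-08, but adjusted p = 0.32 with an estimated correlation). HSPA1A, which can share reads with HSPA1B, had 123 ± 6.41 CPM against 43.8 ± 12.2 CPM (SD, n = 3 each), and the co-chaperone DNAJB1 had 449 ± 6.86 CPM against 279 ± 17.9 CPM. Tubulins and actins were higher in 10 of 13 and lower in 1 (median 0.36, camera adjusted p = 0.00011, but adjusted p = 0.35 with an estimated correlation). TUBB4B had 856 ± 34.9 CPM against 557 ± 38.6 CPM. Ligands of the EGF receptor family were lower in 5 of 7 and higher in 0 (median -0.56, camera adjusted p = 0.0019, but adjusted p = 0.15 with an estimated correlation). That median was the value of BTC, which did not pass and had 0.33 CPM against 0.47 CPM. Low levels were also those of AREG, which did not pass (0.31 against 0.40 CPM), and of NRG1, which did (0.33 against 1.86 CPM). EREG, the epiregulin gene, had 186 ± 14.1 CPM against 472 ± 35.1 CPM in the libraries labelled control.

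The list of the unfolded protein response and amino acid stress was also examined in parts. Its amino acid response part was lower in 18 of 21 members and higher in 1 (median -0.82, camera adjusted p = 3.14e-13, but adjusted p = 0.22 with an estimated correlation). TRIB3, a target of ATF4, had 482 ± 25.3 CPM in the libraries labelled ADH4-overexpressing against 870 ± 131 CPM, and ATF5 was the 1 higher member. The endoplasmic reticulum chaperones were higher in 6 of 13 and lower in 4 and were not called (median 0.15, camera adjusted p = 0.46). Of 12 NRF2 targets picked from the longer list, a choice that left out SLC7A11 (-2.15) and HMOX1 (0.87), 7 were higher and 1 lower (camera adjusted p = 0.021, but adjusted p = 0.21 with an estimated correlation). The difference between these parts was not tested.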
